A study of Homo sapiens with 124 samples.

How the data were processed

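RNA of Treg and Teff subsets sorted from the peripheral blood of healthy donors was measured on 124 whole-transcript Affymetrix arrays, 1 per sorted sample, in 42 groups per the labels. The deposited table holds intensities that the authors made with RMA and Affymetrix Power Tools, per the submitters' processing notes. The versions and settings of these tools are not given in the sources used here. The deposited intensities lie between 0.551 and 8405, a linear scale, and their quantiles differ between arrays, so the arrays do not share 1 distribution. Their log2 was taken here, although the design had assumed that the deposited values were log2 values, and nothing else was done to normalize them. The correlation between arrays of 1 group lay between 0.966 and 0.993, and no 2 arrays held identical values. Arrays give no count of molecules, so their number sets the precision.

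Of 22148 probes, 19129 carried 1 gene symbol in the annotation table, 1735 several and 1284 none. Only probes with 1 symbol were used, since the others name no single gene. For 19099 of them the symbol was looked up by gene identifier in a RefSeq table, and 0 changed. 23 probes of Y-linked genes and of the RNAs that govern X inactivation were left out because the samples come from donors. The 19106 probes kept stand for 18254 genes, and the probe with the highest mean over all arrays was used for the 625 genes with more than 1. A few genes, among them those of some sorted markers, were not analysed here. No array was left out.

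Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 124 arrays, so that groups of 2 to 4 arrays share 1 estimate of spread (82 residual and 6.91 prior degrees of freedom). A lone array left in a group when another is left out is thereby assumed to vary like the other groups. Each contrast used arrays of its own sorting panel. In panels that combine 2 markers, each marker was averaged over the levels of the other, and their interaction was tested. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The series design says that each subset came from 3 different donors, and the labels do not say whether equal replicate numbers are 1 donor, so p-values measure the spread between these samples. The tests, lists, naming rule and most alternatives were chosen before the data were examined.

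Replicate numbers were checked for pairing by correlating the deviations of arrays from their group means across genes. In 13 of 17 panels at least 3 numbers were shared and every pair of same-numbered arrays correlated above 0.1, so a fit with the number as a block is given beside results whose call or count it moves. In the core panel these correlations lay between 0.11 and 0.58. This pairing comes from the data, not from the labels.

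Genes were named by rule: the genes of the sorted markers, the 10 largest changes per direction among called genes without overlap between the groups in the core comparisons, 5 per direction in the others (no overlap within each level of the other marker where averaged) and 3 per direction in interactions, and the 2 to 4 members with the lowest p of a list described, for which overlap was allowed. Not every gene of the rule is printed. Gene lists were tested with camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the residuals, adjusted over 702 tests of 26 lists in 27 comparisons; every list call described passed both ways on all arrays, and the p given is that with the estimated correlation. Counts of members are given over all genes and adjusted over the list alone. With the number of measured members and the number of these that another list also holds, the lists were Treg signature (25, 9), conventional T cell (15, 5), naive and quiescent T cell (20, 3), memory and effector T cell (22, 5), activated Treg (21, 17), class II antigen presentation (9, 5), cell cycle (36, 0), Th1 (18, 8), Th2 (12, 2), Th17 (22, 5), follicular helper (17, 6), inhibitory receptors (14, 8), cytotoxic (19, 8), skin homing (11, 5), gut homing (8, 3), interferon response (25, 0), immediate early genes (24, 0), glycolysis (19, 0) and cholesterol synthesis (15, 0), and for other cell types B cell (12, 0), monocyte and granulocyte (17, 1), dendritic cell (11, 1), NK cell (12, 4), CD8 T cell (8, 4), platelet (13, 0) and erythroid (9, 0).

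Alternatives were a fit on the arrays of 1 panel, the replicate block, genes with a mean at or above the 40th percentile, quantile normalization, the mean of a gene's probes, fry in place of camera, and each array left out in turn. The upper quartile of an array as a covariate, and for CD38 the block with quantile normalization and a fit without both arrays numbered 3, were added after seeing the data, as were list tests with an estimated correlation under alternatives or without the sorted marker. Other splits of the arrays were refitted, at most 100 per comparison. Correlations of log2 changes between panels were set against regroupings of either panel's arrays, 50 drawn for averaged comparisons. Simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 18254 tested the scripts, not the power on real arrays. For ICOS, CD195 and CD39 85%, 66% and 95% of the 2-fold changes were called. Of the 4-fold changes 100% were, with 15, 7 and 18 unchanged genes.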

Results

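Whole-transcript arrays measured RNA of regulatory (Treg) and effector (Teff) T cells sorted from the blood of healthy people. The arrays formed 42 groups in 17 sorting panels, 4 groups with 2 arrays, 36 with 3 and 2 with 4. One panel (labelled d1, meaning not given) held naive-type (CD45RO-) and memory-type (CD45RO+) Treg and Teff. In the other 16 CD45RO+ Treg were divided by surface markers. The log2 median of an array lay between 4.64 and 5.53, and the log2 upper quartile over all probes between 6.43 and 7.58. The number of arrays limits the precision of every value. Changes are log2 differences ± SE from limma on 18254 genes, with p-values adjusted over all genes of a comparison. Genes named for the size of their change were those whose arrays did not overlap between the compared groups, and dim marks a gene with a mean below the 40th percentile, where a low level is not told from background. Beside the p of a gene list, up to gives its highest value without 1 array and then over the other alternatives, with an estimated correlation chosen after seeing the data. Only 12 of the 81 list calls kept to 0.05 in both. Beside a count stand alternatives (the covariate is the upper quartile) that moved it over 1.5 times, or the share of higher genes, from 10 genes on, by over 10 percentage points, and the extremes of arrays left out. Before quantile normalization, which brought these medians near 0, the median change of all genes was 0.10 for memory-type Treg against Teff, 0.12 for memory-type against naive-type Treg and -0.14 for CD38.

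**Figure D1:**
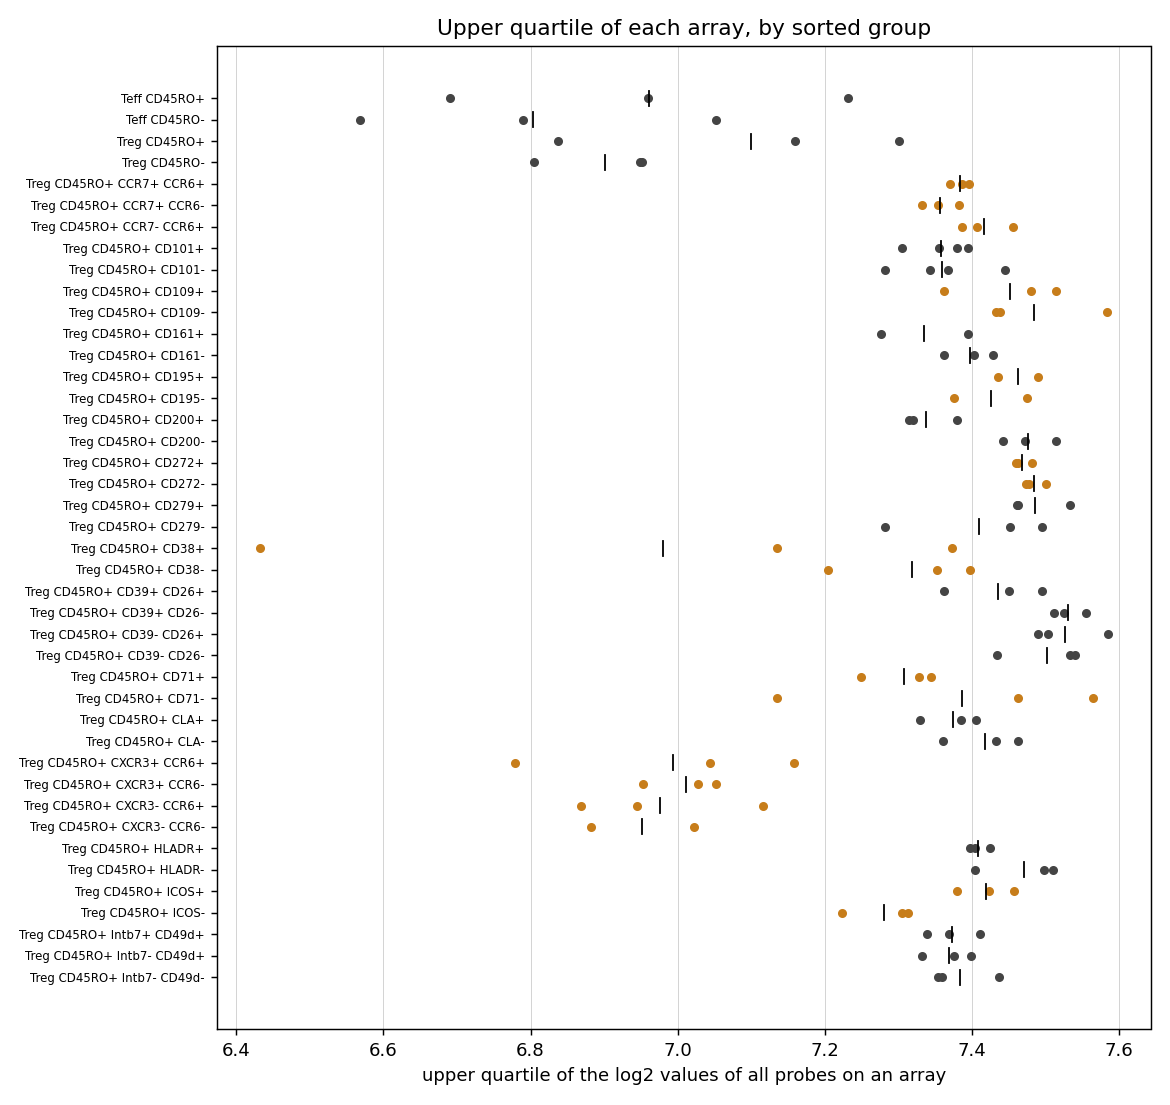
Upper quartile of the log2 values of all probes on each array, by sorted group. Points are arrays, vertical ticks group means, and the 2 colours only part neighbouring panels. The lowest point, at 6.43, is a CD38+ array.

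The first question was what separates naive-type Treg from naive-type Teff (3 and 3 arrays). FOXP3, the transcription factor that defines the Treg lineage, was higher in Treg 48.5-fold (log2 5.60 ± 0.27, adjusted p = 3.1e-32). IKZF2, which encodes the transcription factor Helios, was higher 47.6-fold (log2 5.57 ± 0.18, adjusted p = 1.2e-45), and TIGIT, an inhibitory receptor, 42.8-fold (log2 5.42 ± 0.22, adjusted p = 4.6e-37). The interleukin-2 receptor chains rose, IL2RA (4.40 ± 0.35) and IL2RB (3.77 ± 0.17), with FCRL3 (5.47 ± 0.48), RBMS3 (4.63 ± 0.52), RTKN2 (4.13 ± 0.31) and NCF4 (3.53 ± 0.26). On the lower side stood DSC1 (-3.82 ± 0.36, dim), NELL2 (-3.31 ± 0.59), KRT73 (-3.06 ± 0.34, dim) and CD226 (-2.32 ± 0.27), the last encoding an activating receptor that shares ligands with TIGIT. In the Treg signature list 15 of 25 members rose (18 when adjusted over the list alone, camera adjusted p = 2.4e-09, up to 2.6e-07 and 0.0039). Of the conventional T cell list 7 of 15 members fell (8 when adjusted over the list alone, camera adjusted p = 0.0014, up to 0.011 and 0.078), among them ABCB1 (-2.06 ± 0.23, dim) and THEMIS (-2.07 ± 0.38). In the memory and effector list 9 of 22 members rose (11 when adjusted over the list alone, camera adjusted p = 0.0035, up to 0.028 and 0.11), with CCR4, a receptor for skin-homing chemokines, at 2.40 ± 0.21, while 1 member fell. The activated Treg list (5 of 21 passing, 8 when adjusted over the list alone, camera adjusted p = 0.019, up to 0.055 and 0.12) and the follicular helper list (5 of 17 passing, 5 when adjusted over the list alone, camera adjusted p = 0.013, up to 0.067 and 0.12) were higher, the latter with TOX (2.02 ± 0.20) and CXCR5 (2.63 ± 0.47). limma called 529 genes (353 higher, 176 lower). The arrays of the groups did not overlap in 316 of the higher and 155 of the lower genes, which the call itself favours. The count was 172 with only the panel's arrays, 1084 with the replicate block, 472 (367 higher) without dim genes, 671 (361 higher) with the covariate, 341 (192 higher) without Teff CD45RO- replicate 2, and 629 (515 higher) without Teff CD45RO- replicate 3.

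The same contrast in memory-type cells (3 and 3 arrays) had Treg lineage genes higher again. FOXP3 was higher 59.4-fold (log2 5.89 ± 0.27, adjusted p = 1.4e-33), IKZF2 38.0-fold (log2 5.25 ± 0.18, adjusted p = 1.6e-43) and IL2RA 11.6-fold (log2 3.53 ± 0.35, adjusted p = 3.0e-13). ENTPD1, which encodes the ectonucleotidase CD39, rose 13.3-fold (log2 3.73 ± 0.79, adjusted p = 5.0e-04), and TNFRSF9, the costimulatory receptor 4-1BB, 13.2-fold (log2 3.72 ± 0.50, adjusted p = 2.2e-08). Other genes with large rises were ST8SIA6 (4.87 ± 0.39), TRIB1 (4.47 ± 0.30), TTN (4.11 ± 0.31) and CCDC141 (4.04 ± 0.29). The chemokine gene CCL5 was lower 16.2-fold (log2 -4.02 ± 0.59, adjusted p = 2.2e-07), as were ADAM23 (-4.93 ± 0.32, dim), NELL2 (-4.67 ± 0.59), CR1 (-4.16 ± 0.43, dim), PTPN13 (-3.42 ± 0.43) and THEMIS (-3.24 ± 0.38), a gene of T cell receptor signalling. Of the Treg signature list 23 of 25 members rose (24 when adjusted over the list alone, camera adjusted p = 5.4e-08, up to 1.9e-06 and 0.0039). In the conventional T cell list 8 of 15 members fell (8 when adjusted over the list alone, camera adjusted p = 3.3e-06, up to 2.8e-05 and 0.039), including IL7R, the interleukin-7 receptor chain that Treg carry at low levels, at -2.04 ± 0.22. Of the class II antigen presentation list 7 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 0.0032, up to 0.016 and 0.068), with HLA-DMA (2.64 ± 0.30) and HLA-DPA1 (2.04 ± 0.29). In the activated Treg list 16 of 21 members rose (17 when adjusted over the list alone, camera adjusted p = 1.0e-04, up to 6.3e-04 and 0.040), and of the naive and quiescent list 6 of 20 members fell (8 when adjusted over the list alone, camera adjusted p = 0.044, up to 0.11 and 0.20) while 2 rose. limma called 1269 genes (851 higher, 418 lower). The count was 509 with only the panel's arrays, 2483 with the replicate block, 1595 (761 higher) with quantile normalization, 1621 (836 higher) with the covariate, 720 (403 higher) without Treg CD45RO+ replicate 1, 1054 (564 higher) without Teff CD45RO+ replicate 1, and 1504 (1212 higher) without Teff CD45RO+ replicate 3.

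Memory-type Treg were then set against naive-type Treg (3 and 3 arrays). PRDM1, which encodes the effector regulator BLIMP1, was higher 9.22-fold (log2 3.20 ± 0.27, adjusted p = 2.0e-16), and HLA-DPA1 9.68-fold (log2 3.27 ± 0.29, adjusted p = 6.3e-16). HPGD, an enzyme that degrades prostaglandin E2, was higher 13.2-fold (log2 3.72 ± 0.54, adjusted p = 1.6e-07), with ST8SIA6 (3.65 ± 0.39), SLC1A4 (3.25 ± 0.33), TNFRSF9 (3.09 ± 0.50) and KLRB1 (3.06 ± 0.43). The growth factor receptor gene IGF1R was lower 14.4-fold (log2 -3.85 ± 0.50, adjusted p = 5.6e-09), and PECAM1, the adhesion molecule CD31 of recent thymic emigrants, 8.44-fold (log2 -3.08 ± 0.48, adjusted p = 1.0e-06), with NOG (-3.61 ± 0.50), AK5 (-3.09 ± 0.50, dim), PLAC8 (-2.96 ± 0.47) and RASGRF2 (-2.91 ± 0.45). PTPRC, which encodes CD45, stood at 0.01 ± 0.09 (adjusted p = 0.96) at the gene level, CD45RO being a splice form. In the memory and effector list 17 of 22 members rose (19 when adjusted over the list alone, camera adjusted p = 9.3e-05, up to 6.3e-04 and 0.051), and of the naive and quiescent list 12 of 20 members fell (14 when adjusted over the list alone, camera adjusted p = 2.9e-04, up to 9.6e-04 and 0.078), with SATB1 (-1.82 ± 0.25), TXK (-1.92 ± 0.31) and APBA2 (-3.34 ± 0.45). In the skin homing list 7 of 11 members rose (9 when adjusted over the list alone, camera adjusted p = 6.7e-04, up to 0.0032 and 0.039), including the chemokine receptors CCR4 (2.67 ± 0.21), CCR6 (2.71 ± 0.34) and CCR8 (3.01 ± 0.40). Of the class II list 7 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 0.0067, up to 0.021 and 0.081), in the activated Treg list 14 of 21 members rose (15 when adjusted over the list alone, camera adjusted p = 9.3e-04, up to 0.0029 and 0.068), and of the conventional T cell list 5 of 15 members fell (7 when adjusted over the list alone, camera adjusted p = 0.018, up to 0.055 and 0.12) while 1 rose. limma called 2142 genes (1703 higher, 439 lower). The count was 767 with only the panel's arrays, 3575 with the replicate block, 2405 (1245 higher) with quantile normalization, 2485 (1418 higher) with the covariate, and 1247 without Treg CD45RO+ replicate 1.

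In Teff, memory-type cells were compared with naive-type cells (3 and 3 arrays). KLRB1, which encodes the lectin receptor CD161, was higher 22.8-fold (log2 4.51 ± 0.43, adjusted p = 2.8e-14), CCL5 21.7-fold (log2 4.44 ± 0.59, adjusted p = 6.2e-09) and CCR4 17.2-fold (log2 4.10 ± 0.21, adjusted p = 2.7e-30). GZMK, a granzyme of cytotoxic granules, rose 14.0-fold (log2 3.81 ± 0.83, adjusted p = 5.4e-04), with B3GALT2 (4.26 ± 0.43), PTPN13 (4.14 ± 0.43), NIBAN1 (4.08 ± 0.23) and TIGIT (3.68 ± 0.22). PECAM1 was lower 13.7-fold (log2 -3.78 ± 0.48, adjusted p = 2.4e-09), with KRT73 (-4.07 ± 0.34, dim), NOG (-3.86 ± 0.50), DSC1 (-2.90 ± 0.36, dim) and NRCAM (-2.75 ± 0.29, dim). PTPRC stood at 0.03 ± 0.09 (adjusted p = 0.91). In the memory and effector list 18 of 22 members rose (20 when adjusted over the list alone, camera adjusted p = 5.4e-08, up to 2.8e-06 and 0.034), and of the naive and quiescent list 11 of 20 members fell (14 when adjusted over the list alone, camera adjusted p = 0.0040, up to 0.020 and 0.12). Helper lineage lists were higher as well. In the Th1 list 10 of 18 members rose (12 when adjusted over the list alone, camera adjusted p = 0.013, up to 0.057 and 0.13), with CXCR3 (2.88 ± 0.34) and IL18R1 (1.60 ± 0.26). Of the Th17 list 10 of 22 members rose (14 when adjusted over the list alone, camera adjusted p = 4.2e-04, up to 0.0043 and 0.081), with MAF (2.85 ± 0.24) and CCR6 (3.54 ± 0.34). In the follicular helper list 7 of 17 members rose (8 when adjusted over the list alone, camera adjusted p = 6.7e-04, up to 0.0065 and 0.044), with TOX (2.02 ± 0.20). The skin homing list (3 of 11 passing, 4 when adjusted over the list alone, camera adjusted p = 0.025, up to 0.072 and 0.093) lost its call under the replicate block (adjusted p = 0.093). limma called 1282 genes (975 higher, 307 lower). The count was 515 with only the panel's arrays, 2286 with the replicate block, 1760 (971 higher) with quantile normalization, 1513 (827 higher) with the covariate, and 895 (544 higher) without Teff CD45RO+ replicate 3.

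**Figure D2:**
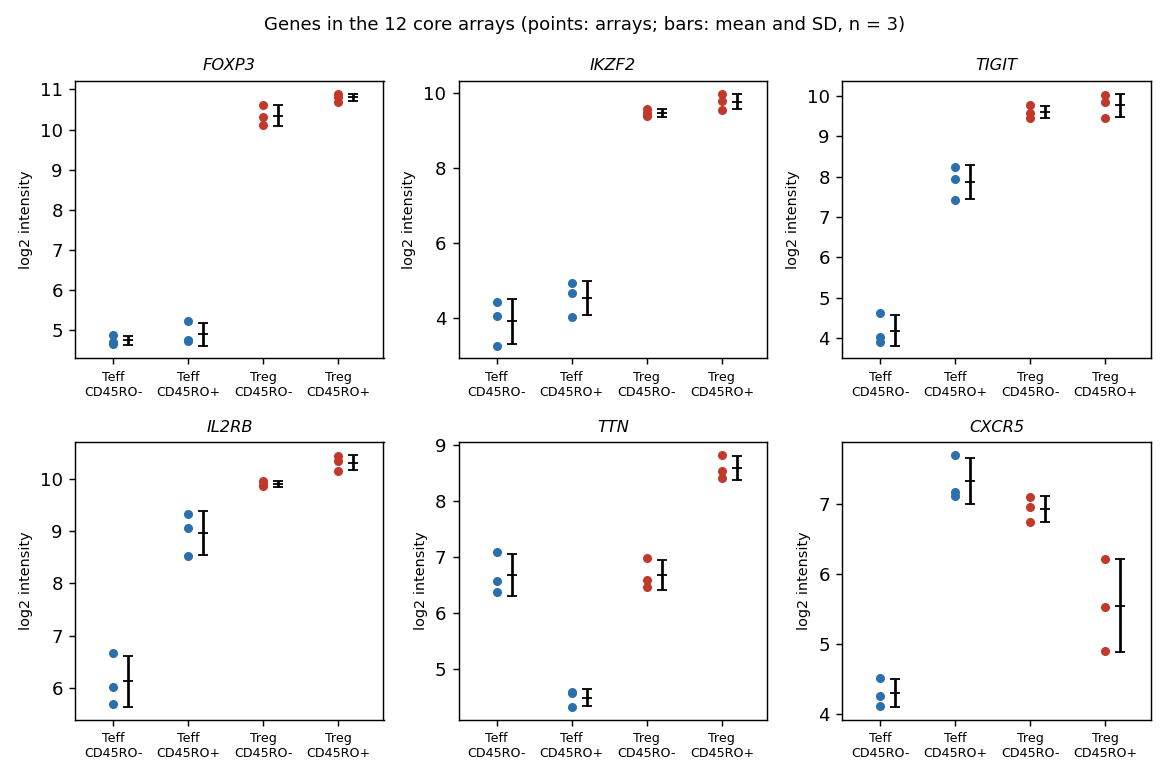
Log2 intensity of 6 genes named in the core comparisons in CD45RO- and CD45RO+ Teff and Treg; points are arrays, bars the mean and SD (n = 3). FOXP3 and IKZF2 separate the lineages at both CD45RO levels, TIGIT and IL2RB lie lowest in CD45RO- Teff, TTN is highest in CD45RO+ Treg, and CXCR5 is higher with CD45RO in Teff and lower in Treg.

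Some differences between Treg and Teff depended on CD45RO, tested as an interaction over the 12 arrays, where a positive value means a larger Treg excess in memory-type cells. CCDC141 and TTN had the largest positive values, CCDC141 (4.17 ± 0.41, adjusted p = 1.3e-12) and TTN (4.11 ± 0.44, adjusted p = 2.0e-11), then ST8SIA6, a sialyltransferase gene, 3.39 ± 0.55 (adjusted p = 2.4e-05). CXCR5, the receptor that guides T cells to B cell follicles, had the largest negative value, -4.41 ± 0.66 (adjusted p = 3.6e-06), followed by ADAM23 (-3.73 ± 0.45, adjusted p = 2.3e-09, dim) and TIGIT (-3.51 ± 0.32, adjusted p = 2.7e-14). Of the class II list 4 of 9 members had positive values (7 when adjusted over the list alone, camera adjusted p = 0.0035, up to 0.021 and 0.068), with HLA-DMA (2.91 ± 0.43), HLA-DPA1 (2.23 ± 0.40) and HLA-DMB (2.17 ± 0.44). In the follicular helper list 4 of 17 members had negative values (5 when adjusted over the list alone, camera adjusted p = 0.012, up to 0.048 and 0.068). limma called 205 genes (96 higher, 109 lower). The count was 69 with only the panel's arrays, 746 with the replicate block, 439 with quantile normalization, 361 with the covariate, 134 (44 higher) without Treg CD45RO+ replicate 1, and 159 (99 higher) without Teff CD45RO+ replicate 3.

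**Figure D3:**
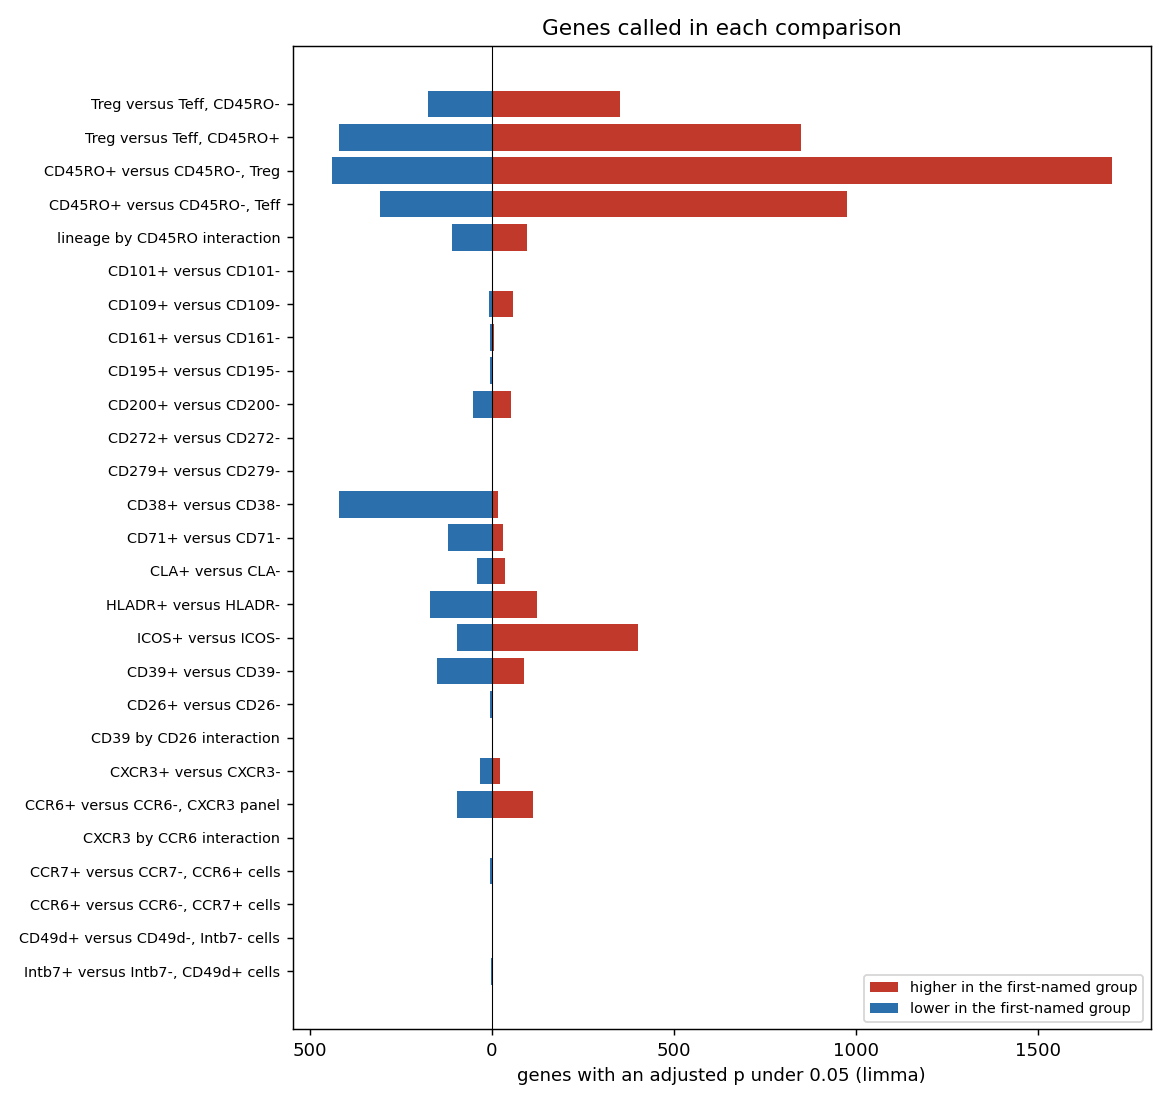
Number of genes with an adjusted p under 0.05 in limma in each comparison; bars to the right count genes higher in the first-named group and bars to the left genes lower in it. The longest bars are those of memory-type against naive-type Treg, with 2142 genes, and CD101 and both marker interactions have 0.

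The next comparisons asked what each surface marker separates among CD45RO+ Treg. CD101, an immunoglobulin family receptor, stood at 0.80 ± 0.81 (adjusted p = 1.0) in CD101+ against CD101- cells (4 and 4 arrays), and no gene list passed with an estimated correlation. limma called 0 of 18254 genes, with 126 at an unadjusted p under 0.05 and 0 under the replicate block.

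CD109+ Treg (3 and 3 arrays) carried more transcripts of dividing cells. CD109, a surface protein that binds transforming growth factor beta, was higher 5.20-fold (log2 2.38 ± 0.27, adjusted p = 2.5e-09, dim). MKI67, the proliferation marker Ki-67, rose 4.97-fold (log2 2.31 ± 0.44, adjusted p = 0.0011), and CCNB2, a mitotic cyclin, 4.39-fold (log2 2.14 ± 0.40, adjusted p = 9.1e-04, dim), with the histone gene H1-5 (1.80 ± 0.31). Of the cell cycle list 15 of 36 members rose (23 when adjusted over the list alone, camera adjusted p = 0.0013, up to 0.0081 and 0.16), among them the mitotic kinase gene PLK1 (1.26 ± 0.23) and the checkpoint kinase gene BUB1B (1.12 ± 0.22, dim). The Th2 list was higher as a set (1 of 12 passing, 5 when adjusted over the list alone, camera adjusted p = 0.017, up to 0.20 and 0.25). Of the fallen genes KRTAP5-AS1 (-1.52 ± 0.30) changed most. limma called 64 genes (58 higher, 6 lower). The count was 2 (1 higher) with only the panel's arrays, 301 (208 higher) with the replicate block, 25 (20 higher) without dim genes, 58 (42 higher) with quantile normalization, 98 (76 higher) with the covariate, and 24 without CD109- replicate 3. With only the panel's arrays no cell cycle gene was called. The call was lost for MKI67 without CD109- replicate 1 or CD109+ replicate 2 (adjusted p = 0.056 to 0.057), and PLK1 without CD109+ replicate 2 (0.055). Without some array 6 of the 10 genes named for size lost the call.

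CD161+ Treg (2 and 3 arrays) had higher Th17 genes and a lower Treg signature. KLRB1, which encodes CD161, was higher 35.1-fold (log2 5.13 ± 0.49, adjusted p = 4.0e-13). PTPN13, a phosphatase gene, rose 7.02-fold (log2 2.81 ± 0.48, adjusted p = 2.9e-04), and IL23R, the interleukin-23 receptor of Th17 cells, 3.16-fold (log2 1.66 ± 0.37, adjusted p = 0.035, dim). IKZF2 fell 2.51-fold (log2 -1.33 ± 0.20, adjusted p = 1.7e-05), as did RTKN2 (-1.57 ± 0.35). In the Th17 list 3 of 22 members rose (7 when adjusted over the list alone, camera adjusted p = 3.3e-06, up to 8.0e-04 and 0.10), and of the Treg signature list 2 of 25 members fell (7 when adjusted over the list alone, camera adjusted p = 0.0035, up to 0.29 and 0.37). The class II list (0 of 9 passing, 2 when adjusted over the list alone, camera adjusted p = 0.030, up to 0.24 and 0.16) and the CD8 T cell list (0 of 8 passing, 1 when adjusted over the list alone, camera adjusted p = 0.035, up to 0.34 and 0.19) were lower as sets, their median changes -0.67 (-0.42 without CD161+ replicate 1) and -0.46. limma called 12 genes (8 higher, 4 lower). The count was 1 with only the panel's arrays, 12 (6 higher) without dim genes, 1 without CD161+ replicate 1, and 11 (9 higher) without CD161- replicate 1. limma no longer called PTPN13 and IKZF2 without CD161+ replicate 1 (adjusted p = 0.68 and 0.89), IL23R without any of 4 of the 5 arrays (0.20 to 1.0), and RTKN2 without any of the 5 arrays (0.058 to 1.0). Without some array 8 of the 9 genes named for size lost the call.

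In CD195+ Treg (2 and 2 arrays) CCR2 rose 15.5-fold (log2 3.95 ± 0.82, adjusted p = 0.022) and CXCR6 5.56-fold (log2 2.47 ± 0.38, adjusted p = 5.7e-05), both chemokine receptors, while RNF144A fell 5.23-fold (log2 -2.39 ± 0.39, adjusted p = 3.0e-04) and the chromatin remodeller CHD7 3.82-fold (log2 -1.93 ± 0.34, adjusted p = 0.0012). The gene of CD195 was not analysed here. In the gut homing list 2 of 8 members rose (2 when adjusted over the list alone, camera adjusted p = 2.7e-04, up to 0.0067 and 0.34), with a median of 0.66, 0.38 without CD195+ replicate 2 and 1.03 without CD195+ replicate 1. The memory and effector, activated Treg, class II and skin homing lists were higher as sets (camera adjusted p = 0.034, up to 0.44 and 0.55; 0.019, up to 0.17 and 0.35; 0.037, up to 0.65 and 0.55; and 0.030, up to 0.18 and 0.35) with 0 members passing over all genes and 0, 1, 4 and 0 when adjusted over the list alone. limma called 6 genes (2 higher, 4 lower). The count was 12 with the covariate and 0 without CD195+ replicate 2. The call ended for CCR2 without any of the 4 arrays (adjusted p = 0.13 to 1.0), CXCR6 and RNF144A without CD195+ replicate 2 (0.21 and 0.21), and CHD7 without CD195- replicate 2 or CD195+ replicate 2 (0.11 to 0.40). Without some array 6 of the 6 genes named for size lost the call.

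CD200+ Treg (3 and 3 arrays) were lower in class II genes. CD200, a ligand that inhibits myeloid cells, was higher 21.4-fold (log2 4.42 ± 0.49, adjusted p = 5.0e-10), and CCR9, the receptor of small intestinal homing, 4.03-fold (log2 2.01 ± 0.46, adjusted p = 0.018). PI16, a peptidase inhibitor gene, fell 6.91-fold (log2 -2.79 ± 0.46, adjusted p = 2.4e-04), with LINC02694 (-2.05 ± 0.35), MSC (-2.02 ± 0.37) and CAMTA1 (-1.55 ± 0.26). Of the class II list 2 of 9 members fell (6 when adjusted over the list alone, camera adjusted p = 0.023, up to 0.11 and 0.35), HLA-DPA1 (-1.36 ± 0.29) and HLA-DMB (-1.25 ± 0.31). In the memory and effector list 2 of 22 members fell (11 when adjusted over the list alone, camera adjusted p = 0.033, up to 0.11 and 0.29), a call that ended under the replicate block (adjusted p = 0.054). limma called 105 genes (53 higher, 52 lower). The count was 38 (15 higher) with only the panel's arrays, 639 with the replicate block, 92 (32 higher) without dim genes, 74 (27 higher) with quantile normalization, 13 (5 higher) without CD200- replicate 1, 39 (12 higher) without CD200- replicate 2, and 263 (199 higher) without CD200- replicate 3. The threshold was missed by CCR9 and HLA-DMB without any of 4 of the 6 arrays (adjusted p = 0.072 to 0.11 and 0.051 to 0.25), and HLA-DPA1 without CD200- replicate 1 or CD200+ replicate 2 (0.080 to 0.14). Without some array 4 of the 10 genes named for size lost the call.

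In CD272+ Treg (3 and 3 arrays) follicular helper genes were higher. BTLA, which encodes CD272, rose 4.13-fold (log2 2.05 ± 0.34, adjusted p = 4.4e-04) and CD200 9.16-fold (log2 3.20 ± 0.49, adjusted p = 6.6e-05), with SPON1 (2.07 ± 0.44) and ENPP2 (1.05 ± 0.21, dim). Of the follicular helper list 2 of 17 members rose (7 when adjusted over the list alone, camera adjusted p = 2.9e-04, up to 0.020 and 0.18), and in the inhibitory receptor list 2 of 14 members rose (2 when adjusted over the list alone, camera adjusted p = 0.0067, up to 0.033 and 0.16), in both cases CD200 and BTLA. Without BTLA, the sorted marker, the inhibitory receptor list missed the threshold (adjusted p = 0.062). The conventional T cell list (0 of 15 passing, 6 when adjusted over the list alone, camera adjusted p = 4.2e-04, up to 0.014 and 0.068) and the naive and quiescent list (0 of 20 passing, 6 when adjusted over the list alone, camera adjusted p = 0.0099, up to 0.20 and 0.18) were higher as sets, with median changes of 0.64 (0.37 without CD272- replicate 2) and 0.34. limma called 5 genes (5 higher, 0 lower). The count was 24 with only the panel's arrays, 150 (116 higher) with the replicate block, 16 (13 higher) with quantile normalization, 19 (16 higher) with the covariate, and 2 without CD272- replicate 2. No longer called were SPON1 without any of 5 of the 6 arrays (adjusted p = 0.052 to 0.36), and ENPP2 without any of 4 of the 6 arrays (0.096 to 0.21). Without some array 3 of the 5 genes named for size lost the call.

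In CD279+ Treg (3 and 3 arrays) the follicular helper list was higher (0 of 17 passing, 9 when adjusted over the list alone, camera adjusted p = 2.1e-04, up to 0.0060 and 0.18), as were the cytotoxic (0 of 19 passing, 7 when adjusted over the list alone, camera adjusted p = 0.0099, up to 0.53 and 0.35), Th1 (0 of 18 passing, 6 when adjusted over the list alone, camera adjusted p = 0.033, up to 0.22 and 0.33) and Th2 lists (0 of 12 passing, 2 when adjusted over the list alone, camera adjusted p = 0.041, up to 0.56 and 0.50). Among their members CD200 stood at 2.24 ± 0.49 (adjusted p = 0.11, with the replicate block 0.0022) and NKG7, a gene of cytotoxic granules, at 1.12 ± 0.31 (adjusted p = 0.41). DTHD1 rose 3.93-fold (log2 1.97 ± 0.37, adjusted p = 0.016, dim). The gene of CD279 was not analysed here. limma called 1 gene, DTHD1, with 511 at an unadjusted p under 0.05. The count was 0 with only the panel's arrays, 41 with the replicate block, 0 without dim genes, 0 without CD279- replicate 2, and 21 without CD279+ replicate 1. The call was lost for DTHD1 without any of 3 of the 6 arrays (adjusted p = 0.081 to 1.0).

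CD38+ Treg (3 and 3 arrays) had more genes lower than higher. CD38, an NAD-consuming ectoenzyme, rose 6.96-fold (log2 2.80 ± 0.48, adjusted p = 6.8e-04), CCR9 4.21-fold (log2 2.07 ± 0.46, adjusted p = 0.0099) and GZMK 7.03-fold (log2 2.81 ± 0.83, adjusted p = 0.046). CAMTA1, a transcription activator gene, fell 3.30-fold (log2 -1.72 ± 0.26, adjusted p = 4.1e-05), and TGFBR3, a coreceptor of transforming growth factor beta, 2.96-fold (log2 -1.56 ± 0.28, adjusted p = 7.7e-04), with LMNA, a gene of the nuclear lamina, at -1.43 ± 0.33. None of the 26 lists passed with an estimated correlation. limma called 437 genes (17 higher, 420 lower). CD38+ replicate 3 had the lowest upper quartile of all arrays. The count was 0 with only the panel's arrays, 2490 with the replicate block, 930 without dim genes, 15 (4 higher) with quantile normalization, 3 (1 higher) with the covariate, 2 without CD38+ replicate 3, and 4250 without CD38+ replicate 1. limma no longer called CCR9 without any of 3 of the 6 arrays (adjusted p = 0.091 to 0.27), GZMK without any of 4 of the 6 arrays (0.10 to 1.0), TGFBR3 without CD38+ replicate 3 (0.66), and LMNA without CD38- replicate 1 or CD38+ replicate 3 (0.15 to 0.75). Without some array 8 of the 10 genes named for size lost the call.

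CD71+ Treg (3 and 3 arrays) had higher class II genes. MKI67 rose 4.26-fold (log2 2.09 ± 0.44, adjusted p = 0.0061), and HLA-DOA, a class II chaperone gene, 2.64-fold (log2 1.40 ± 0.31, adjusted p = 0.012). The small nucleolar RNA SNORD116-1 of an imprinted cluster fell 5.11-fold (log2 -2.35 ± 0.44, adjusted p = 0.0016), with SNORD116-14 (-1.89 ± 0.38) of the same cluster and PLAC8 (-2.21 ± 0.47). TFRC, the transferrin receptor CD71, stood at 0.70 ± 0.20 (adjusted p = 0.067) and passed under the replicate block (adjusted p = 0.015). Of the class II list 2 of 9 members rose (6 when adjusted over the list alone, camera adjusted p = 0.020, up to 0.083 and 0.16), and the activated Treg list was higher as a set (0 of 21 passing, 9 when adjusted over the list alone, camera adjusted p = 0.023, up to 0.071 and 0.12). limma called 151 genes (31 higher, 120 lower). The count was 29 (3 higher) with only the panel's arrays, 846 with the replicate block, 202 (70 higher) with quantile normalization, 252 (89 higher) with the covariate, 12 without CD71+ replicate 1, 46 (19 higher) without CD71- replicate 1, and 414 without CD71- replicate 3. The call ended for MKI67 without CD71+ replicates 1 or 2 (adjusted p = 0.059 to 0.065), HLA-DOA without any of 4 of the 6 arrays (0.062 to 0.096), SNORD116-14 without CD71+ replicate 1 (0.059), and PLAC8 without CD71- replicate 2 or CD71+ replicate 1 (0.069 to 0.076). Without some array 9 of the 10 genes named for size lost the call.

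CLA marks skin-homing cells, and CLA+ Treg (3 and 3 arrays) were higher in skin homing genes. FUT7, the fucosyltransferase that makes CLA, rose 3.07-fold (log2 1.62 ± 0.21, adjusted p = 5.1e-07), and CCR10, a skin chemokine receptor, 4.34-fold (log2 2.12 ± 0.34, adjusted p = 5.5e-05). PI16 was higher 6.82-fold (log2 2.77 ± 0.46, adjusted p = 9.7e-05), with MSC (2.04 ± 0.37) and CDC42BPB (1.95 ± 0.30). The carrier protein gene SELPLG stood at 0.25 ± 0.13 (adjusted p = 0.42). ITGA4, the integrin chain CD49d, fell 8.06-fold (log2 -3.01 ± 0.52, adjusted p = 3.1e-04), and CCR9 7.13-fold (log2 -2.83 ± 0.46, adjusted p = 9.7e-05), with CD38 (-2.55 ± 0.48). In the skin homing list 2 of 11 members rose (4 when adjusted over the list alone, camera adjusted p = 0.0099, up to 0.037 and 0.35), and of the class II list 3 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 0.012, up to 0.049 and 0.12), with HLA-DOA (1.73 ± 0.31) and HLA-DPA1 (1.37 ± 0.29). Without FUT7 and SELPLG the skin homing list missed the threshold (adjusted p = 0.054) at an unchanged median of 0.38. limma called 78 genes (38 higher, 40 lower). The count was 164 with only the panel's arrays, 687 (258 higher) with the replicate block, 119 without dim genes, 135 with quantile normalization, 154 with the covariate, 17 (10 higher) without CLA- replicate 3, 41 (25 higher) without CLA+ replicate 3, and 82 (29 higher) without CLA+ replicate 2. The threshold was missed by HLA-DPA1 without CLA- replicate 3 or CLA+ replicate 1 (adjusted p = 0.058 to 0.10). Without some array 3 of the 10 genes named for size lost the call.

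HLADR+ Treg (3 and 3 arrays) were higher across the class II genes. HLA-DMB rose 5.05-fold (log2 2.33 ± 0.31, adjusted p = 4.0e-07), HLA-DMA 4.24-fold (log2 2.08 ± 0.30, adjusted p = 3.3e-06) and HLA-DQA1 6.74-fold (log2 2.75 ± 0.62, adjusted p = 0.0054), with CCR10 (2.35 ± 0.34) and LINC02694 (2.35 ± 0.35). PLAC8 fell 10.7-fold (log2 -3.42 ± 0.47, adjusted p = 7.3e-07) and CXCR5 6.60-fold (log2 -2.72 ± 0.47, adjusted p = 1.2e-04), with RASGRF2 (-2.98 ± 0.45) and IGF1R (-2.69 ± 0.50). In the class II list 7 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 1.0e-04, up to 2.9e-04 and 0.078), and of the activated Treg list 8 of 21 members rose (11 when adjusted over the list alone, camera adjusted p = 0.019, up to 0.051 and 0.23). The naive and quiescent list (4 of 20 passing, 6 when adjusted over the list alone, camera adjusted p = 0.037, up to 0.071 and 0.23) and the conventional T cell list (2 of 15 passing, 6 when adjusted over the list alone, camera adjusted p = 0.026, up to 0.092 and 0.16) were lower, with APBA2 (-2.17 ± 0.45) and BACH2 (-1.28 ± 0.27). limma called 296 genes (126 higher, 170 lower). The count was 481 with only the panel's arrays, 1026 with the replicate block, and 101 without HLADR- replicate 2. No longer called were HLA-DQA1 without HLADR- replicate 3 or HLADR+ replicate 1 (adjusted p = 0.057).

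ICOS+ Treg (3 and 3 arrays) had higher class II and cell cycle genes. ICOS, the inducible costimulator, rose 1.36-fold (log2 0.45 ± 0.11, adjusted p = 0.017) and CD38 4.29-fold (log2 2.10 ± 0.48, adjusted p = 0.0081). NEIL3, a repair enzyme gene of dividing cells, was higher 4.12-fold (log2 2.04 ± 0.28, adjusted p = 1.0e-06), and SKA3, a kinetochore gene, 5.06-fold (log2 2.34 ± 0.32, adjusted p = 1.0e-06, dim), with TSHR (1.98 ± 0.36). IGF1R fell 4.39-fold (log2 -2.13 ± 0.50, adjusted p = 0.0093), with RNF144A (-1.67 ± 0.32) and RIMKLB (-1.65 ± 0.36). In the cell cycle list 11 of 36 members rose (22 when adjusted over the list alone, camera adjusted p = 0.047, up to 0.086 and 0.33), with NUSAP1 (1.81 ± 0.31) and KIF11 (1.72 ± 0.33). Of the class II list 4 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 0.030, up to 0.10 and 0.14), led by HLA-DMA (1.96 ± 0.30), and in the activated Treg list 6 of 21 members rose (10 when adjusted over the list alone, camera adjusted p = 0.020, up to 0.055 and 0.085). limma called 496 genes (402 higher, 94 lower). The count was 1100 with only the panel's arrays, 2286 with the replicate block, 917 (491 higher) with quantile normalization, 524 (294 higher) with the covariate, and 70 without ICOS+ replicate 1. The call was lost for ICOS without any of 4 of the 6 arrays (adjusted p = 0.057 to 0.14), CD38 and IGF1R without any of 3 of the 6 arrays (0.054 to 0.078 and 0.061 to 0.10), and RIMKLB without ICOS- replicate 2 (0.058). Without some array 5 of the 10 genes named for size lost the call.

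In 1 panel CD39 and CD26 were combined, and each was compared within the levels of the other (6 and 6 arrays). CD39+ cells had more of the Treg signature. ENTPD1, which encodes CD39, rose 6.17-fold (log2 2.62 ± 0.56, adjusted p = 0.0025), CCR8, a receptor of tissue Treg, 3.46-fold (log2 1.79 ± 0.28, adjusted p = 2.2e-05), and LAYN, a hyaluronan receptor gene, 3.72-fold (log2 1.90 ± 0.30, adjusted p = 2.5e-05). PTPN13 fell 3.92-fold (log2 -1.97 ± 0.30, adjusted p = 1.8e-05) and GZMK 4.90-fold (log2 -2.29 ± 0.58, adjusted p = 0.020), with RASGRF2 (-1.74 ± 0.32) and RNF130 (-1.68 ± 0.26). Of the Treg signature list 8 of 25 members rose (17 when adjusted over the list alone, camera adjusted p = 0.0013, up to 0.0065 and 0.037), with TRIB1 (1.0 ± 0.21) and CSF2RB (1.28 ± 0.27). In the class II list 7 of 9 members rose (7 when adjusted over the list alone, camera adjusted p = 7.4e-05, up to 3.0e-04 and 0.037), and of the activated Treg list 9 of 21 members rose (16 when adjusted over the list alone, camera adjusted p = 9.0e-04, up to 0.0053 and 0.078). The conventional T cell list (4 of 15 passing, 10 when adjusted over the list alone, camera adjusted p = 4.4e-04, up to 0.0015 and 0.040) and the naive and quiescent list (3 of 20 passing, 8 when adjusted over the list alone, camera adjusted p = 0.033, up to 0.11 and 0.13) were lower, with THEMIS (-1.49 ± 0.27) and SERINC5 (-0.69 ± 0.13). limma called 237 genes (88 higher, 149 lower). The count was 730 with the replicate block and 139 without CD39+ CD26- replicate 2. limma no longer called GZMK without any of 5 of the 12 arrays (adjusted p = 0.070 to 0.092). Without some array 2 of the 10 genes named for size lost the call.

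CD26+ cells of this panel (6 and 6 arrays) were lower in cell cycle genes as a set. DPP4, the peptidase CD26, rose 4.79-fold (log2 2.26 ± 0.36, adjusted p = 1.8e-04). NCALD, a calcium sensor gene, fell 2.19-fold (log2 -1.13 ± 0.20, adjusted p = 0.0025), and PCLAF, a replication gene, 1.93-fold (log2 -0.95 ± 0.21, adjusted p = 0.041, dim). The cell cycle list (0 of 36 passing, 19 when adjusted over the list alone, camera adjusted p = 0.013, up to 0.041 and 0.16) and the class II list (0 of 9 passing, 5 when adjusted over the list alone, camera adjusted p = 0.024, up to 0.089 and 0.044) were lower. The conventional T cell list (0 of 15 passing, 0 when adjusted over the list alone, camera adjusted p = 0.045, up to 0.17 and 0.11) and the Th17 list (1 of 22 passing, 3 when adjusted over the list alone, camera adjusted p = 0.049, up to 0.18 and 0.25) were higher, the latter with DPP4 as its passing member and an adjusted p = 0.063 under the replicate block and 0.14 without DPP4. limma called 7 genes (2 higher, 5 lower). The count was 20 (9 higher) with only the panel's arrays, 177 with the replicate block, 2 (1 higher) without dim genes, 3 (2 higher) with quantile normalization, 2 without CD39- CD26- replicate 1, and 16 without CD39+ CD26- replicate 2. The call ended for PCLAF without any of 9 of the 12 arrays (adjusted p = 0.058 to 0.31). Without some array 4 of the 6 genes named for size lost the call. For the interaction of CD39 with CD26 limma called 0 genes, with 507 at an unadjusted p under 0.05 and 0 under the replicate block.

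CXCR3 and CCR6 were combined in another panel. CXCR3+ cells (6 and 5 arrays) were higher in Th1 genes and lower in Th2 genes. CXCR3, a Th1 chemokine receptor, rose 5.26-fold (log2 2.40 ± 0.26, adjusted p = 1.8e-10), GZMK 31.9-fold (log2 5.0 ± 0.62, adjusted p = 3.0e-08), CCL5 7.81-fold (log2 2.97 ± 0.44, adjusted p = 7.8e-06) and IL12RB2, an interleukin-12 receptor chain, 6.15-fold (log2 2.62 ± 0.39, adjusted p = 7.8e-06). HPGDS, a prostaglandin D synthase, fell 9.01-fold (log2 -3.17 ± 0.60, adjusted p = 0.0020, dim) and IL9R, the interleukin-9 receptor, 3.43-fold (log2 -1.78 ± 0.26, adjusted p = 7.8e-06), with IL17RB (-2.54 ± 0.50). In the Th1 list 5 of 18 members rose (6 when adjusted over the list alone, camera adjusted p = 0.0010, up to 0.018 and 0.037). Of the Th2 list 5 of 12 members fell (8 when adjusted over the list alone, camera adjusted p = 0.0019, up to 0.076 and 0.14), including GATA3, the Th2 regulator, at -0.60 ± 0.12. limma called 55 genes (23 higher, 32 lower). The count was 18 (10 higher) with only the panel's arrays, 46 (27 higher) without dim genes, 149 with quantile normalization, 83 with the covariate, 17 without CXCR3- CCR6+ replicate 2, 39 (10 higher) without CXCR3- CCR6- replicate 2, 40 (32 higher) without CXCR3- CCR6- replicate 1, and 109 (61 higher) without CXCR3+ CCR6+ replicate 2. The threshold was missed by HPGDS and IL17RB without CXCR3- CCR6- replicate 1 (adjusted p = 0.079 and 0.11), and GATA3 without CXCR3- CCR6- replicate 1 or CXCR3- CCR6+ replicate 2 (0.054 to 0.10). Without some array 4 of the 10 genes named for size lost the call.

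CCR6+ cells of the same panel (6 and 5 arrays) had higher memory and class II genes and lower naive genes. CCR6, a receptor of Th17 cells, rose 3.27-fold (log2 1.71 ± 0.25, adjusted p = 7.9e-06), though its arrays overlapped between the groups. HLA-DPA1 was higher 3.08-fold (log2 1.62 ± 0.21, adjusted p = 5.8e-07), with PI16 (1.55 ± 0.34), LINC02694 (1.48 ± 0.26) and CCR8 (1.35 ± 0.30). IGF1R fell 4.54-fold (log2 -2.18 ± 0.37, adjusted p = 2.1e-04), with RBMS3 (-2.14 ± 0.39), APBA2 (-1.88 ± 0.34) and CXCR5 (-1.58 ± 0.35). In the memory and effector list 5 of 22 members rose (13 when adjusted over the list alone, camera adjusted p = 0.0034, up to 0.015 and 0.12), with CCR4 (1.04 ± 0.15) and S100A10 (0.59 ± 0.11). Of the naive and quiescent list 5 of 20 members fell (8 when adjusted over the list alone, camera adjusted p = 0.033, up to 0.12 and 0.063), and in the conventional T cell list 2 of 15 members fell (7 when adjusted over the list alone, camera adjusted p = 0.0080, up to 0.086 and 0.12). Class II (4 of 9 passing, 6 when adjusted over the list alone, camera adjusted p = 0.0032, up to 0.016 and 0.068), activated Treg (6 of 21 passing, 13 when adjusted over the list alone, camera adjusted p = 0.0061, up to 0.023 and 0.040) and skin homing genes (4 of 11 passing, 7 when adjusted over the list alone, camera adjusted p = 0.0080, up to 0.030 and 0.12) were higher. limma called 209 genes (115 higher, 94 lower). The count was 138 (56 higher) with only the panel's arrays, 782 with quantile normalization, 464 with the covariate, 102 without CXCR3- CCR6+ replicate 1, and 168 (130 higher) without CXCR3- CCR6- replicate 1. No longer called were PI16 without CXCR3- CCR6+ replicate 1 (adjusted p = 0.055), and CXCR5 without CXCR3- CCR6- replicate 1 (0.075). The interaction of CXCR3 with CCR6 gave 0 genes in limma, with 943 at an unadjusted p under 0.05. The count was 23 with quantile normalization, 3 with the covariate, and 26 without CXCR3- CCR6- replicate 1.

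Within CCR6+ Treg, CCR7+ cells were set against CCR7- cells (3 and 3 arrays). CCR7, the lymph node homing receptor, rose 2.25-fold (log2 1.17 ± 0.19, adjusted p = 3.4e-04), CD38 7.47-fold (log2 2.90 ± 0.48, adjusted p = 3.4e-04) and CCR9 5.01-fold (log2 2.32 ± 0.46, adjusted p = 0.013), with TXK, a T cell kinase gene, at 1.51 ± 0.31. ATP10D fell 2.54-fold (log2 -1.34 ± 0.23, adjusted p = 3.4e-04). Of the naive and quiescent list 2 of 20 members rose (3 when adjusted over the list alone, camera adjusted p = 0.0012, up to 0.013 and 0.068), CCR7 and TXK. limma called 8 genes (4 higher, 4 lower). The count was 61 (15 higher) with the replicate block and 4 without CCR7+ CCR6+ replicate 1. The call was lost for CCR9 without any of 3 of the 6 arrays (adjusted p = 0.12 to 0.25), and TXK without any of 4 of the 6 arrays (0.056 to 1.0). Without some array 5 of the 8 genes named for size lost the call.

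Within CCR7+ Treg, CCR6+ cells (3 and 3 arrays) were higher in CCR6 5.80-fold (log2 2.54 ± 0.34, adjusted p = 9.7e-07) and in HLF, a transcription factor gene, 3.99-fold (log2 2.0 ± 0.32, adjusted p = 1.5e-04). In the Th17 list 1 of 22 members rose (10 when adjusted over the list alone, camera adjusted p = 2.8e-05, up to 6.3e-04 and 0.051), the sorted CCR6, without which the adjusted p was 1.4e-04. CCL20, the ligand of CCR6, stood at 2.03 ± 0.45 (adjusted p = 0.063, with the replicate block 0.0046). The memory and effector (0 of 22 passing, 4 when adjusted over the list alone, camera adjusted p = 0.013, up to 0.14 and 0.34), skin homing (1 of 11 passing, 3 when adjusted over the list alone, camera adjusted p = 0.0099, up to 0.078 and 0.40), activated Treg (0 of 21 passing, 0 when adjusted over the list alone, camera adjusted p = 0.022, up to 0.19 and 0.35), gut homing (0 of 8 passing, 1 when adjusted over the list alone, camera adjusted p = 0.020, up to 0.079 and 0.16) and class II lists (0 of 9 passing, 1 when adjusted over the list alone, camera adjusted p = 0.037, up to 0.19 and 0.19) were higher as sets, though fry missed the threshold for the last 2, and the median of the class II list was 0.40 to 0.93 without single arrays. The passing member of the skin homing list was CCR6, and without it the list missed the threshold (adjusted p = 0.096). limma called 2 genes (2 higher, 0 lower), CCR6 and HLF. The count was 70 (45 higher) with the replicate block, 6 with quantile normalization, 7 with the covariate, and 15 without CCR7+ CCR6- replicate 1.

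The last panel divided Treg by the integrin chains CD49d and beta 7. In cells without beta 7, ITGA4, which encodes CD49d, was higher in CD49d+ cells 8.64-fold (log2 3.11 ± 0.52, adjusted p = 9.6e-04), although the arrays of the groups overlapped (3 and 3 arrays). limma called 1 gene, ITGA4, with 279 at an unadjusted p under 0.05. The count was 0 with only the panel's arrays and 2 without Intb7- CD49d- replicate 2. limma no longer called ITGA4 without Intb7- CD49d- replicates 1 or 3 (adjusted p = 1.0). Among CD49d+ cells, those with beta 7 (3 and 3 arrays) were higher in the gut homing receptor CCR9 31.9-fold (log2 4.99 ± 0.46, adjusted p = 1.8e-13) and in CD38 5.37-fold (log2 2.43 ± 0.48, adjusted p = 0.013), with LZTFL1 (1.23 ± 0.24) and PCDH1 (0.85 ± 0.18, dim). ITGB1, the alternative partner of CD49d, fell 2.40-fold (log2 -1.26 ± 0.19, adjusted p = 1.4e-05). ITGB7, the gene of the sorted chain, stood at 0.33 ± 0.19 (adjusted p = 1.0). Of the gut homing list 1 of 8 members rose (1 when adjusted over the list alone, camera adjusted p = 2.7e-04, up to 0.0051 and 0.41). limma called 5 genes (4 higher, 1 lower). The count was 0 with only the panel's arrays and 1 without Intb7+ CD49d+ replicate 3. The call ended for CD38 and LZTFL1 without any of 4 of the 6 arrays (adjusted p = 0.087 to 1.0 and 0.087 to 1.0), PCDH1 without any of 5 of the 6 arrays (0.087 to 1.0), and ITGB1 without Intb7+ CD49d+ replicate 3 (0.052).

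Over all comparisons camera called 240 of 702 list tests with a preset correlation of 0.01, and 81 of these held with an estimated correlation. These are the list calls given for the single comparisons. On all arrays the class II list held in 14 comparisons, the activated Treg list in 10, and the conventional and naive lists in 8 each. The first 2 are not separate, as 5 of the 21 activated Treg members are class II members. In 15 of these calls the list holds a gene of the sorted marker, and 11 held without it. Lists of interferon response, immediate early, glycolysis, cholesterol synthesis, B cell, monocyte and granulocyte, dendritic cell, NK cell, platelet and erythroid genes held in none (lowest adjusted p = 0.070 with an estimated correlation).

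**Figure D4:**
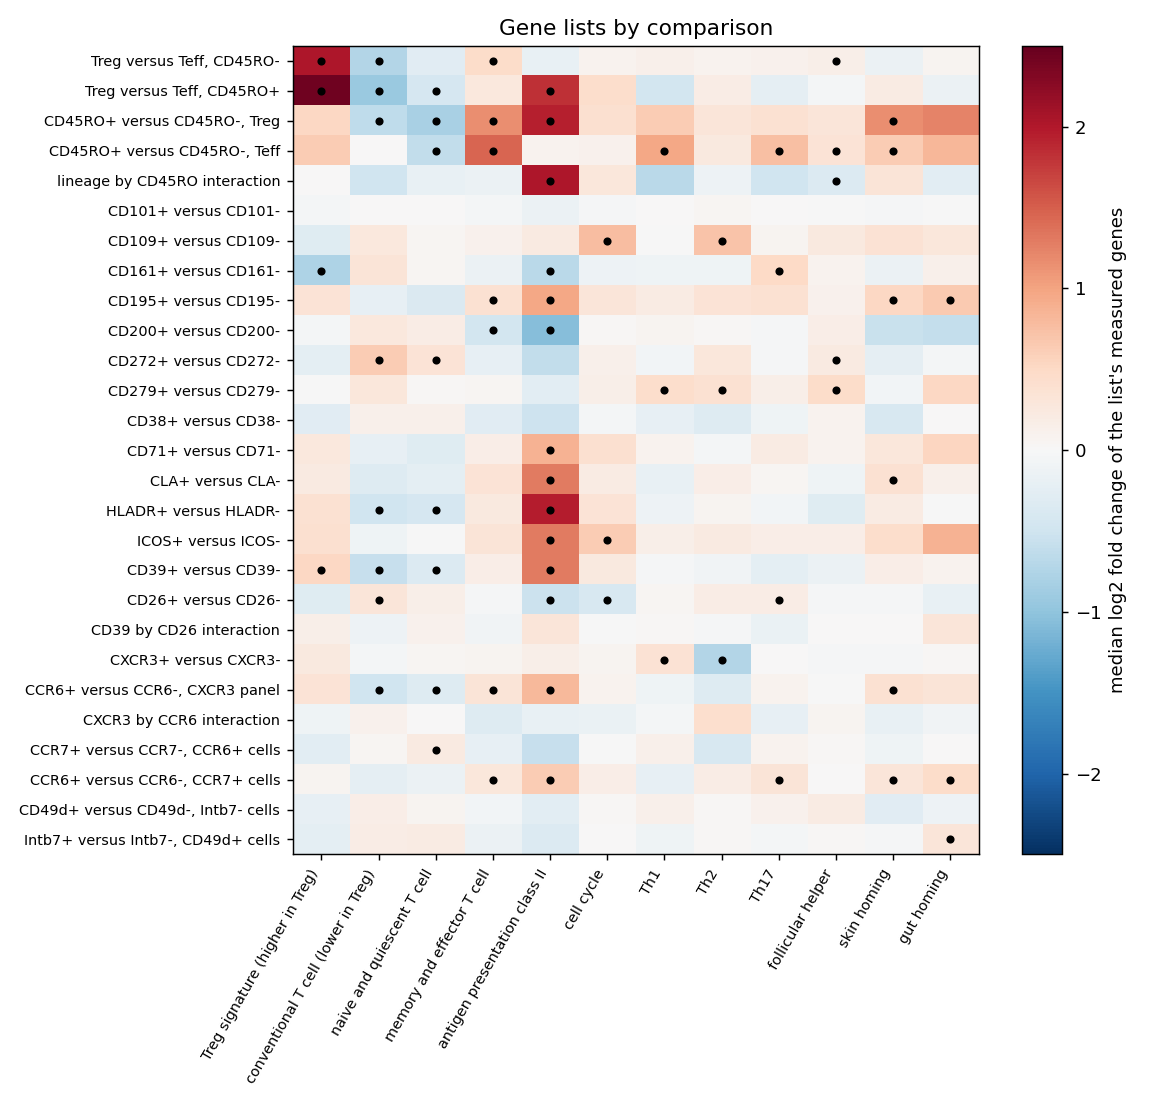
Median log2 change of the measured genes of 12 gene lists (columns) in each comparison; red is higher in the first-named group, and dots are camera calls that held with an estimated correlation. The class II column has 14 dots, its medians below 0 in CD161+, CD200+ and CD26+ cells. Among these dots only that of CD39 stayed under 0.05 both without each array and under every other alternative.

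Log2 changes of 24 comparisons were correlated across genes to find alike ones, for 266 pairs from panels without shared arrays. HLADR+ and CD39+ cells had the most alike changes (r = 0.68, where regroupings of 1 panel's arrays reached 0.61 in size), then CD71+ and HLADR+ cells (0.64 v 0.45) and CD195+ and ICOS+ cells (0.59 v 0.44). The step from naive-type to memory-type Treg went with CCR6 in the CXCR3 panel (0.58 v 0.48), and the contrast of memory-type Treg with Teff went with CD39 (0.56 v 0.53) and against CD26 (-0.45 v 0.38). CD200+ cells resembled CD38+ cells (0.47 v 0.45) and ran against ICOS+ cells (-0.43 v 0.40). The 2 CCR6 comparisons, from different panels, gave 0.50 v 0.44. In 50 pairs r lay beyond all other regroupings of 1 panel's arrays, 36 positive and 14 negative, where 10.9 would be reached if the real grouping ranked at random. Genes are not independent replicates, and regroupings carry part of the real contrast.

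**Figure D5:**
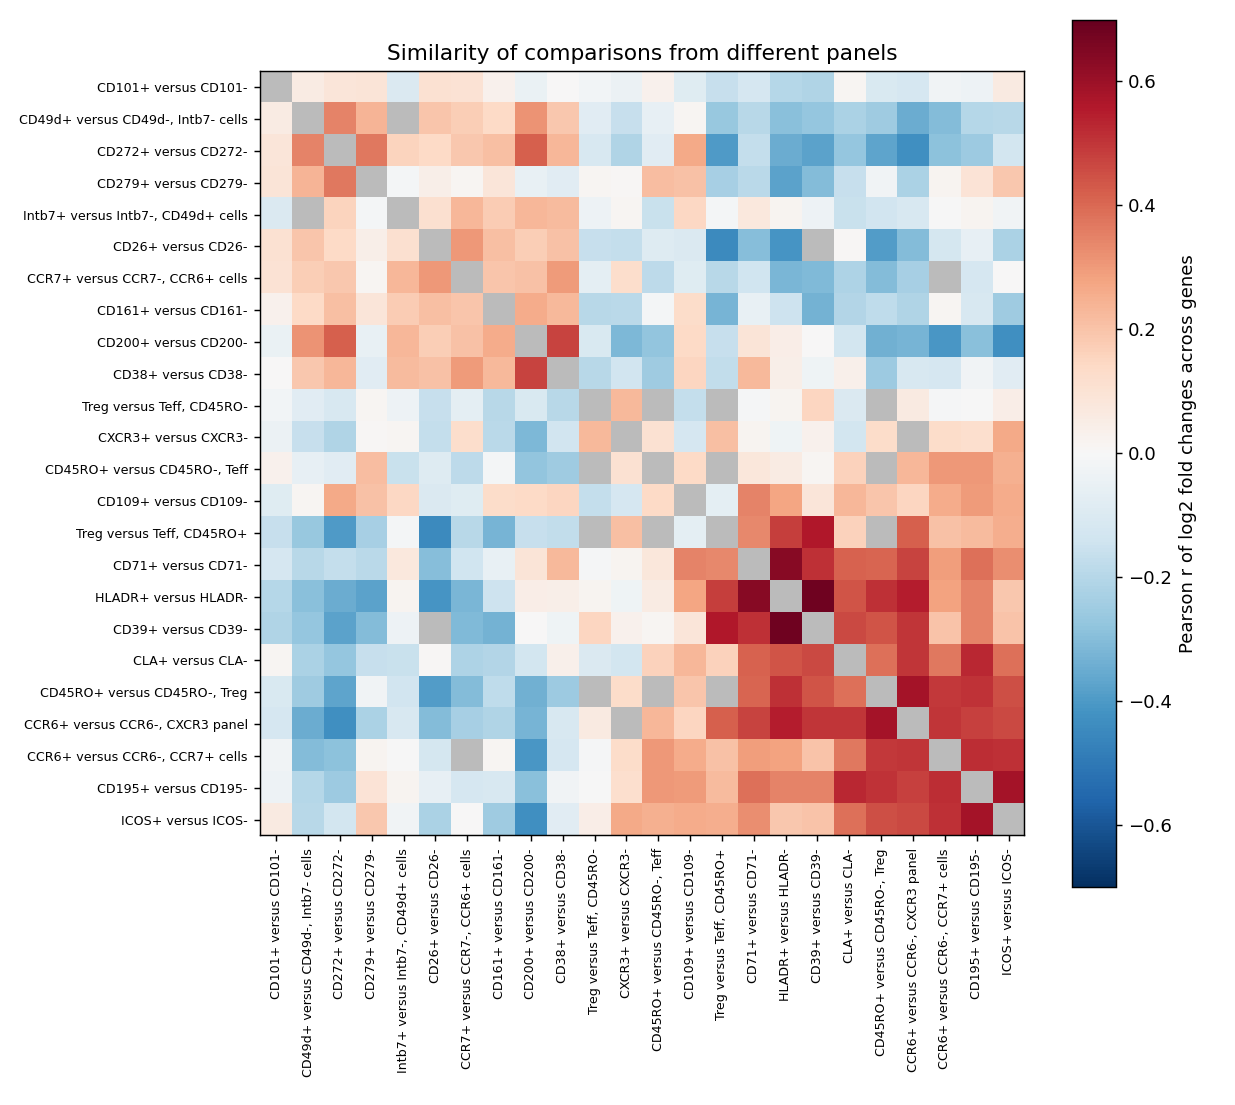
Pearson r across genes between the log2 changes of 24 comparisons; grey cells are pairs of 1 panel, which share arrays. The highest value is 0.68, for HLADR+ with CD39+ cells, and the lowest -0.45.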

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

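The split test in this part was chosen only after the result was seen, and the interaction test was planned. In 205 genes (96 higher, 109 lower) limma called the interaction of lineage and CD45RO over the 12 arrays, so the difference between Treg and Teff was not the same in naive-type and memory-type cells. Of the 61 genes named by rule in the core comparisons, 26 were among them, with adjusted p up to 0.042. The excess in Treg was larger, or the deficit smaller, in memory-type cells for CCDC141 (4.17), TTN (4.11), ST8SIA6 (3.39), LINC02694 (2.93), TNFRSF9 (2.92), HPGD (2.91), FANK1 (2.73), DSC1 (2.49, dim), TRIB1 (2.44), HLA-DPA1 (2.23), DACT1 (2.03, dim) and NRCAM (1.75, dim), log2 differences of differences. It was smaller, or the deficit larger, for MYO1F (-1.23), CCR4 (-1.43), CR1 (-2.21, dim), NCF4 (-2.22), PLAC8 (-2.41), IL2RB (-2.43), RASGRF2 (-2.53), RBMS3 (-2.83), ST6GALNAC2 (-2.85), PRR5L (-2.85), PTPN13 (-3.28), TIGIT (-3.51), ADAM23 (-3.73, dim) and CXCR5 (-4.41).

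Of 100 splits of the 12 arrays into groups of the same sizes, the real one included, 41 gave as many genes, and the highest of the others gave 4451. These splits also carry the contrasts of lineage and CD45RO, so they neither exclude chance for the count nor speak for it. Those that called many times the real count point to this structure of the samples. In the panel with 4 arrays per group, CD101, the marker gene was tested for a lone array in 2 groups, and 0 arrays stood apart.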

How the results depend on the processing

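The covariate, 2 further fits of CD38, the list tests with an estimated correlation under alternatives or without the sorted marker, and the split tests in this part were chosen only after the results were seen. No call changed sign under any alternative in 453 gene results and 81 list results. Of the 341 called gene results, 108 lost the call without some array, 79 with only the panel's arrays, 18 with quantile normalization, 11 with the covariate and 1 with the mean of probes. The mean of a gene's probes kept 27 of 27 counts within 1.5 times. At the preset correlation all 81 list calls passed with only the panel's arrays, quantile normalization, the covariate and the mean of probes. Fry missed 5 of them (class II and CD8 T cell in CD161, Th2 in CD279, class II and gut homing in CCR6 among CCR7+ cells), the fit without dim genes 1 (Th2 in CD279) and the fits without an array 2 (class II in CD195, cytotoxic in CD279). With an estimated correlation, chosen after seeing the data, 81 held with the covariate, 81 with the mean of probes, 79 with quantile normalization (not naive and quiescent in memory-type Treg against Teff, adjusted p = 0.072, and class II in CCR6 among CCR7+ cells, adjusted p = 0.052), 59 without dim genes and 14 with only the panel's arrays, and 40 lost the call without some array.

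With only the arrays of a panel, 7 of 27 counts stayed within 1.5 times; the others were 172 for naive-type Treg against Teff, 509 for memory-type Treg against Teff, 767 for CD45RO in Treg, 515 for CD45RO in Teff, 69 for the lineage interaction, 2 for CD109, 1 for CD161, 38 for CD200, 24 for CD272, 0 for CD279, 0 for CD38, 29 for CD71, 164 for CLA, 481 for HLADR, 1100 for ICOS, 20 for CD26, 18 for CXCR3, 138 for CCR6 (CXCR3 panel), 0 for CD49d and 0 for beta 7, where fewer arrays estimate the spread. With genes at or above the 40th percentile alone, 23 of 28 counts stayed within 1.5 times, and the others were 25 for CD109, 0 for CD279, 930 for CD38, 119 for CLA and 2 for CD26, where fewer genes were tested. Quantile normalization gave 439 for the lineage interaction, 16 for CD272, 15 for CD38, 135 for CLA, 917 for ICOS, 3 for CD26, 149 for CXCR3, 782 for CCR6 (CXCR3 panel), 23 for the CXCR3 by CCR6 interaction and 6 for CCR6 in CCR7+ cells, with 18 of 28 within 1.5 times. The upper quartile covariate, added after seeing the data, gave 361 for the lineage interaction, 98 for CD109, 12 for CD195, 19 for CD272, 3 for CD38, 252 for CD71, 154 for CLA, 83 for CXCR3, 464 for CCR6 (CXCR3 panel), 3 for the CXCR3 by CCR6 interaction and 7 for CCR6 in CCR7+ cells, with 17 of 28 within 1.5 times. For CD38, 2 genes were left without both arrays numbered 3, also added then. For the changes with quantile normalization and the covariate, the cause was not tested.

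With the replicate block the count rose beyond 1.5 times in 23 of 28 results, to 1084 for naive-type Treg against Teff, 2483 for memory-type Treg against Teff, 3575 for CD45RO in Treg, 2286 for CD45RO in Teff, 746 for the lineage interaction, 301 for CD109, 639 for CD200, 150 for CD272, 41 for CD279, 2490 for CD38, 846 for CD71, 687 for CLA, 1026 for HLADR, 2286 for ICOS, 730 for CD39, 177 for CD26, 61 for CCR7 and 70 for CCR6 in CCR7+ cells where the numbers pair the arrays. In the CD161, CD195, CXCR3 and beta 7 panels they share only a number, with fewer than 3 shared numbers or, for beta 7, correlations between -0.03 and 0.38, though there 9 of 9 arrays were closest to 1 of their own number, a hint from the data. The block gave 53 for CD161, 122 for CD195, 310 for CXCR3, 795 for CCR6 (CXCR3 panel) and 1 for the CXCR3 by CCR6 interaction there, and ended the calls of the class II list in CD161 (adjusted p = 0.082) and the skin homing list in CD195 (adjusted p = 0.059). It brought 51 of the 453 gene results past the threshold. Apart from these and the values given with the comparisons, it changed no other call. With quantile normalization added after seeing the data, the block gave 268 for CD38. The cause was not tested.

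Leaving out each array in turn gave counts between 341 and 629 for naive-type Treg against Teff, 720 and 1523 for memory-type Treg against Teff, 1247 and 2428 for CD45RO in Treg, 880 and 1698 for CD45RO in Teff, 134 and 283 for the lineage interaction, 0 and 0 for CD101, 24 and 72 for CD109, 1 and 11 for CD161, 0 and 5 for CD195, 13 and 263 for CD200, 2 and 4 for CD272, 0 and 21 for CD279, 2 and 4250 for CD38, 12 and 414 for CD71, 17 and 82 for CLA, 101 and 282 for HLADR, 70 and 481 for ICOS, 139 and 228 for CD39, 2 and 16 for CD26, 0 and 0 for the CD39 by CD26 interaction, 17 and 109 for CXCR3, 102 and 286 for CCR6 (CXCR3 panel), 0 and 26 for the CXCR3 by CCR6 interaction, 4 and 7 for CCR7, 2 and 15 for CCR6 in CCR7+ cells, 1 and 2 for CD49d, and 1 and 7 for beta 7.

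Other splits of the arrays were counted, the real split included. For CD39 2 of 100 splits gave as many genes as the real 237 (highest other 263, and 1 among the splits that part as many pairs), a share under 0.05. Of 100 splits, as large as the real one were 13 for CD26 (7, highest other 238), 8 for CXCR3 (55, highest other 1000) and 10 for CCR6 (CXCR3 panel) (209, highest other 1118). The shares for CD26, CXCR3 and CCR6 do not exclude chance for these counts. Among splits that part as many pairs the highest other for CD26 gave 1. With a real count of 0 every split is as large, 35 of 35 for CD101 (highest other 801) and 100 each for the interactions of CD39 with CD26 (214) and CXCR3 with CCR6 (715), which tests nothing. Comparisons of 3 with 3 arrays have 10 splits, too few for a share under 0.05; as large were 2 for naive-type Treg against Teff (529, highest other 596), 3 for memory-type Treg against Teff (1269, highest other 2747), 1 for CD45RO in Treg (2142, highest other 315), 3 for CD45RO in Teff (1282, highest other 2913), 1 for CD109 (64, highest other 11), 1 for CD200 (105, highest other 5), 1 for CD272 (5, highest other 3), 4 for CD279 (1, highest other 8), 3 for CD38 (437, highest other 4707), 3 for CD71 (151, highest other 240), 1 for CLA (78, highest other 0), 1 for HLADR (296, highest other 4), 1 for ICOS (496, highest other 0), 1 for CCR7 (8, highest other 1), 2 for CCR6 in CCR7+ cells (2, highest other 7), 5 for CD49d (1, highest other 2) and 1 for beta 7 (5, highest other 1). Where the numbers pair the arrays, the highest other split that parts as many pairs gave 3 for naive-type Treg against Teff, 16 for memory-type Treg against Teff, 7 for CD45RO in Treg, 42 for CD45RO in Teff, 1 for CD38 and 240 for CD71, and 0 for CD109, CD200, CD272, CD279, CLA, HLADR, ICOS, CCR7 and CCR6 in CCR7+ cells; the other splits keep both arrays of a number together. Splits with many more genes than the real one, as for memory-type Treg against Teff, CD45RO in Teff, CD38, CD101, CD26, CXCR3, CCR6 and the marker interactions, point to a structure of the samples.

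Signal over background limits what dim genes can show: the table has no detection calls, so a low value is not told from no expression. Of the genes named for the size of their change, 6 of 20 for CD45RO in Teff, 3 of 10 for CD109 and 4 of 6 for CD26 lay below the 40th percentile of mean signal, and those printed with a change are marked as dim. The similarity of comparisons had 50 pairs beyond every regrouping, and 47 without dim genes, 65 with quantile normalization, 46 with the replicate block and 65 with the covariate.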

Other observations

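The recurrent genes, the tests of 2 relations between panels, and the tests of the single array for CD38 and of other cells for CD109 were chosen only after the result was seen. The other tests were written down before their result was seen, but after the pattern. Across the 20 marker comparisons in 16 panels, limma called 1560 genes in at least 1, 145 in at least 3 and 29 in at least 5, the recurrent genes, some of them named here. HLA-DMB, a class II chaperone gene, was called in 7 comparisons, higher in 6 of them and lower in 1, and HLA-DPA1 in 6, higher in 5. IGF1R, CHD7, SCML1, SBF2 and SOS2 were lower in the marker-positive cells in each of 6 comparisons that called them. GSAP, PRKCE, RIMKLB, RNF130, RNF144A, SNTB1, USP6NL and ZNF506 were lower in each of 5. HLA-DOA, NEIL3, TSHR and HIP1 were higher in each of 5. PCLAF, a gene of DNA replication, was higher in 4 of 5, and the gut receptor gene CCR9 and CD38 each in 4 of 5.

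Over 16 panels, taking 1 marker comparison of each, the log2 changes of CCR9 and CD38 went together (Pearson r = 0.90, 0.93 without the 2 panels farthest from the median, Spearman rho = 0.94). The pair was picked after its values were seen, and 89 of the 406 pairs of the recurrent genes had an r as high, so a permutation p does not measure chance here. Whether 1 program raises both genes cannot be told; the panel sorted on CD38 itself is included, and whether panels share donors is not stated.

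In the same panels the medians of the cell cycle and class II lists correlated with r = 0.62 (0.82 without the 2 panels farthest from the median) and rho = 0.77. This pair too was picked after its values were seen, and 39 of the 325 pairs of lists had an r as high. Dividing Treg may carry more class II transcripts, which stays open.

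In CD38+ cells 420 of 437 called genes were lower, with a median of -0.66. One candidate explanation is the distribution of CD38+ replicate 3, whose upper quartile over the genes tested was 6.39 against 6.54 or more on the other 123 arrays: without it the same genes had a median of -0.33. Another is a trend of these genes with the upper quartile, which in the other panels predicts a median of -0.26, less than was measured. By replicate number the medians were -0.32, -0.54 and -1.15 for 1, 2 and 3. A fall in CD38+ cells and an effect of 1 array cannot be told apart, since the genes were chosen with that array among 3.

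The Treg signature was lower in CD161+ cells, and conventional T cells inside the gate would need a median share of 59.8% to give the fall of 16 signature genes (-11.0 to 82.5% by gene), and would then raise 46 genes at least 4-fold lower in memory-type Treg than Teff by a median of 1.86. The 46, picked by size, had a median of 0.39 (41 above 0). It was 0.21 of the predicted (95% bootstrap interval over genes alone 0.14 to 0.40). This argues against an equal share of memory-type Teff in both CD161+ arrays as the whole cause. Smaller or unequal shares, and conventional cells of a CD161+ profile, which no sample measured, stay open. Upper quartiles differed by -0.06, so the covariate hardly tested the array distribution. It left the signature at -0.76 (camera adjusted p = 5.5e-19 at the preset correlation, 3.5e-24 to 0.37 over all alternatives). A difference of CD161+ Treg stays open on 2 arrays (median -0.23 without CD161+ replicate 1, -1.21 without replicate 2).

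In CD109+ cells 15 cell cycle genes rose, 0 called with only the panel's arrays (all 15 with unadjusted p under 0.05). B, myeloid, NK, CD8 T, platelet or erythroid cells in the gate are argued against: 0 of 7 lists of other cell types were called higher (lowest camera adjusted p = 0.083), 1 of their 81 members passed, and their median changes lay between -0.13 and 0.04. Upper quartiles differed by -0.03, so the covariate hardly tested the array distribution (15 of 15 called, median 1.25 against 1.26). Dividing conventional CD4 T cells in the gate and a larger share of dividing Treg cannot be told apart, since the Treg signature had a median of -0.30 (camera adjusted p = 0.50 with an estimated correlation, 0.0029 at the preset one) and the conventional T cell list 0.27.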
